A study of Mus musculus with 6 samples.

How the data were processed

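Chromatin of MN1-driven mouse myeloid leukaemia cells was immunoprecipitated with an antibody against H3K79me2 (3 libraries) or sequenced as input (3 libraries). Samples were grouped by the antibody and library number in their titles. Per the submitters' processing notes, CASAVA 1.8.2, GSNAP, SAMtools, bedtools 2.25.0 and MACS2 were used and the genome build was mm9; the notes used here give no settings. MACS2 is a peak caller that compares the read pileup of a treated sample with a background estimated from a control. Per the file header, the deposited table gives for each peak its position, length, pileup, −log10 p, fold enrichment and −log10 q, with no column per library, and its name says that the libraries were combined; whether all inputs served as the control is not given in the sources used here.

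The pileup is the coverage signal of the pooled H3K79me2 reads as the peak caller wrote it. Whether it was scaled is not given in the sources used here, so pileups given in reads may not be read counts. The fold enrichment is the authors' ratio of pileup to control background. The −log10 q column is the authors' deposited value of the peak caller's test (its q-value), which compares pooled reads and does not carry the spread between replicates. The −log10 p column was not used. These values are the authors' own for each peak and were used only to describe, rank and filter peaks within this list. The table has no summit column, its lowest −log10 q is 1.02, its narrowest peak 292 bp and its shortest gap 1169 bp, and 1.54% of its pileups read as whole numbers at 2 decimals, which rounding alone would give for some. These fit MACS2's broad mode, in which the pileup and fold of a peak are averages over the whole region and not its highest point. The mode is not given in the sources used here, and a scaled pileup could also read as a fraction. It holds 18992 peaks, none with a repeated start, and in all 18992 the length equals end minus start plus 1. The number of reads per library is not given in the sources used here, so the depth behind each pileup is known only through the pileup itself, which has a median of 27.2 reads and runs from 19 to 280.6.

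A pooled list has no replicate spread, so no test between samples was run. Counts, medians and quartiles describe the list. Intervals of medians come from the exact binomial distribution of ranks and intervals of shares are exact (Clopper-Pearson) 95% intervals. Peaks are not independent molecules or replicates, so these intervals cover counting error only. The density of a chromosome is its number of peaks, or of covered bases, over the distance from its first to its last peak, since chromosome lengths of mm9 were not used here. The relation between width and fold was tested by permuting the folds 100000 times. Alternatives were recomputed with a −log10 q of at least 5 or 10, a fold of at least 4, a width of at least 500 bp, peaks merged across at most 1 or 3 kb, other denominators for X, and with X and Y or the peaks over a high control background left out.

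The control background under each peak was computed as (pileup + 1) / fold − 1, taking it that MACS2 adds 1 to pileup and background before it divides, as it usually does. Its lowest value, 10.5, was shared by many peaks to within 0.1. Numbers of protein-coding genes per chromosome were taken from a RefSeq table of the assembly GRCm38.p6. Its coordinates were not used for the peaks, because the build differs: none of the 12 Y peaks overlapped a protein-coding gene of that table. The 17 gene lists fixed before the data were examined, the share of peaks in genes and the share of genes marked were therefore not tested. As the design provided for a list without gene names, the text names the 5 peaks with the highest fold and the 5 widest, and any other region it names was chosen after the values were seen.

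The computations were tested on simulated data. Control backgrounds made for the 18992 peaks were recovered with a largest error of 6.5e-05. The simulated folds were made with the same formula, so this checks only its inversion and the rounding. Whether the formula holds for the deposited values was not tested. Shuffled folds gave a factor of 0.988 for weak peaks within 3 kb of strong ones, and weak peaks planted beside strong ones gave 5.15. Intervals of the median held the true median in 95.7% of simulated lists of 500 peaks. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.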

Results

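H3K79me2, the dimethyl mark that the methyltransferase DOT1L places on the core of histone H3 and that lies over the 5′ parts of transcribed genes, was mapped by chromatin immunoprecipitation and sequencing in mouse myeloid leukaemias driven by MN1 (meningioma-1). The leukaemias arose in mice that received CMP cells transformed with MN1, on a C57BL/6 background with a floxed Dot1l allele that had not been inactivated. Blasts sorted from the bone marrow were grown for a short time with serum, IL-3, IL-6 and SCF before the chromatin was taken. The series holds 3 H3K79me2 libraries and 3 input libraries, the input being chromatin sequenced without the antibody. The labels do not say whether the numbered libraries came from different mice. The deposited result is 1 list of peaks over the combined libraries, so the comparison it allows is H3K79me2 against the input background, region by region. Neither a value per library nor the number of reads is in the list. The spread between replicates therefore cannot be given for any value, and intervals cover counting error or the spread between peaks only. The list names no genes and an annotation of its build was not used here, so regions are given by their mm9 position and their genes were not assigned.

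H3K79me2 covered long stretches of the leukaemia genome. The list held 18992 peaks on 21 chromosomes, which together covered 222.5 Mb, or 8.71% of the distance between the first and last peak of each chromosome. The median peak was 4.42 kb wide, with quartiles of 1.55 and 13.2 kb. A long tail of wide regions held much of the covered sequence. There were 874 peaks at least 50 kb wide, with 31.7% of the covered bases, and 154 at least 100 kb wide, with 9.84%. The widest 10% of peaks, 1899 regions, held 49.4% of the covered bases. Gaps between neighbouring peaks had a median of 9.01 kb and quartiles of 2.38 and 50.04 kb. Joining peaks at most 3 kb apart left 13365 regions, of which 3666 were made of at least 2 peaks and the most divided held 14.

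Most of the covered sequence lay in a minority of strong regions. The authors' fold enrichment over the control background had a median of 2.28, with quartiles of 1.91 and 4.57, and reached 19.2. The fold and pileup of a peak can be averages over its length, since the calling mode is not given in the sources used here, so a high value does not stand for a summit. The 5571 peaks with a fold of at least 4 made up 29.3% of the list and 64.5% of the covered bases, with a median width of 17.2 kb. The 1240 peaks with a fold of at least 8 had a median width of 24.99 kb, and the 378 with a fold of at least 10 had a median width of 28.01 kb. At the other end, 6608 peaks, 34.8% of the list, had a fold under 2, a median width of 1.33 kb and 5.87% of the covered bases. Regions of at least 4-fold were fewer than those under 2-fold and covered more sequence.

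Wider regions had higher folds. Peaks narrower than 1 kb had a median fold of 1.85, those of 1 to 5 kb 1.98, those of 5 to 20 kb 3.69, those of 20 to 50 kb 5.75 and those of at least 50 kb 6.55. Spearman's rho between width and fold across the 18992 peaks was 0.78 (permutation test with 100000 resamples, two-sided, p = 1e-05, the smallest these resamples can give). Peaks are not independent replicates, and this was the only relation computed between peak properties. Width and fold come from the same peak calls, and calling against a cutoff can itself link them. The permutation takes them as unlinked, so it cannot tell a property of the mark from the calling. Where folds are averages over a region, a wide peak's fold can lie below that of its highest part. Within single chromosomes, Y left out, rho ran from 0.73 on X to 0.79 on chromosome 12. Among the peaks with −log10 q of at least 10, rho was 0.34.

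**Figure D1:**
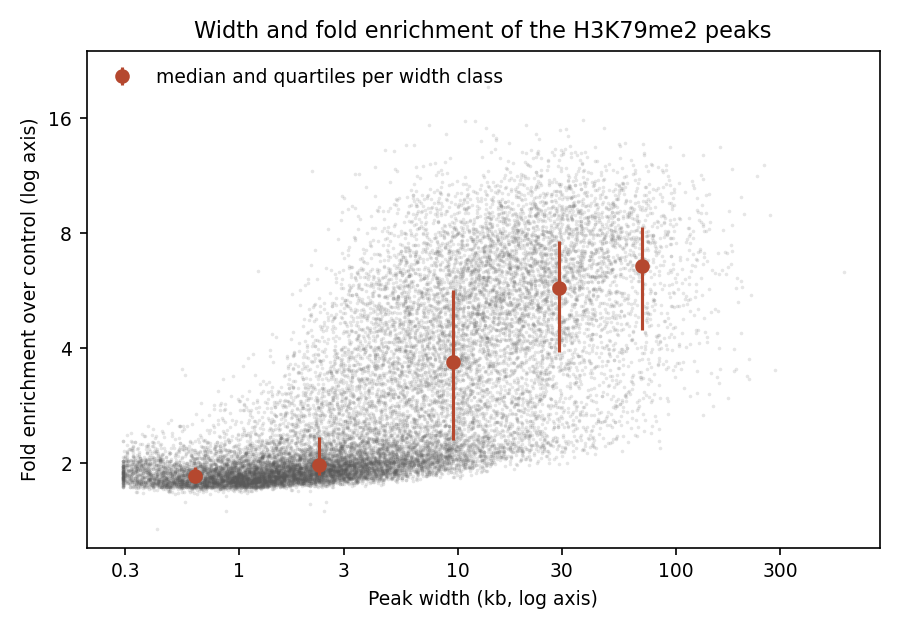
Each grey point is a peak, with its width in kb on the horizontal log axis and the authors' fold enrichment over the control on the vertical log axis. Red points and bars give the median and quartiles of the fold in 5 width classes, drawn at the class's median width, and the median rises from 1.85 below 1 kb to 6.55 at 50 kb and above.

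The strongest H3K79me2 region lay on chromosome 9, from 100975675 to 100989491. It was 13.8 kb wide, with a fold of 19.2, a pooled pileup of 250.4 reads and a −log10 q of 236.1, and its fold was 1.22 times that of the next region. The next was a region of 37.6 kb on chromosome 11, from 75543082 to 75580694, with a fold of 15.8. It was followed by a region of 11.97 kb on chromosome 1, from 9726387 to 9738351, with a fold of 15.7. A region of 10.8 kb on chromosome 19, from 47654245 to 47665047, also reached a fold of 15.7. The fifth, 7.39 kb on chromosome 18 from 54021905 to 54029298, had a fold of 15.4.

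The widest H3K79me2 region lay on chromosome 6, from 98890397 to 99477613. It spanned 587.2 kb, 2.06 times the next widest, with a fold of 6.33 and a −log10 q of 40.6. The second widest was on chromosome 5, from 132657475 to 132942202, with a width of 284.7 kb and a fold of 3.49. The third, from 129099342 to 129370482 on chromosome 1, was 271.1 kb wide with a fold of 8.93. A second region of chromosome 5, from 136792526 to 137045631, was 253.1 kb wide and reached a fold of 12.02. The fifth was also on chromosome 6, from 133982004 to 134217881, with a width of 235.9 kb and a fold of 11.3. None of these 5 was among the 5 strongest.

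Marked sequence gathered in some megabase regions and was missing from others. Across 538 windows of 5 Mb the median share covered was 7.29%, with quartiles of 3.797% and 11.6%, and 25 windows held no covered base. The windows and stretches named here were chosen after their values were seen. The most covered window was 75 to 80 Mb on chromosome 11, at 30.4% and 110 peaks. It was followed by 25 to 30 Mb on chromosome 17 at 29.9% and by 70 to 75 Mb on chromosome 8 at 28.4%. At a scale of 1 Mb, 784 of 2644 windows held no covered base and 19 were covered by at least 40%. Windows of both sizes were counted from position 1, so the empty ones include those before a chromosome's first peak. The most covered windows of 1 Mb were 51 to 52 Mb on chromosome 3 at 67.9%, 106 to 107 Mb on chromosome 11 at 59.3% and 28 to 29 Mb on chromosome 6 at 57.5%. In contrast, 35 stretches of at least 5 Mb held no peak, 253.1 Mb in all. The longest, 15.99 Mb, ran from 110298964 to 126284643 on X, and the next, 12.2 Mb, from 13101305 to 25293462 on chromosome 15. A stretch or window without peaks can also be one where reads could not be placed, which the list does not show.

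**Figure D2:**
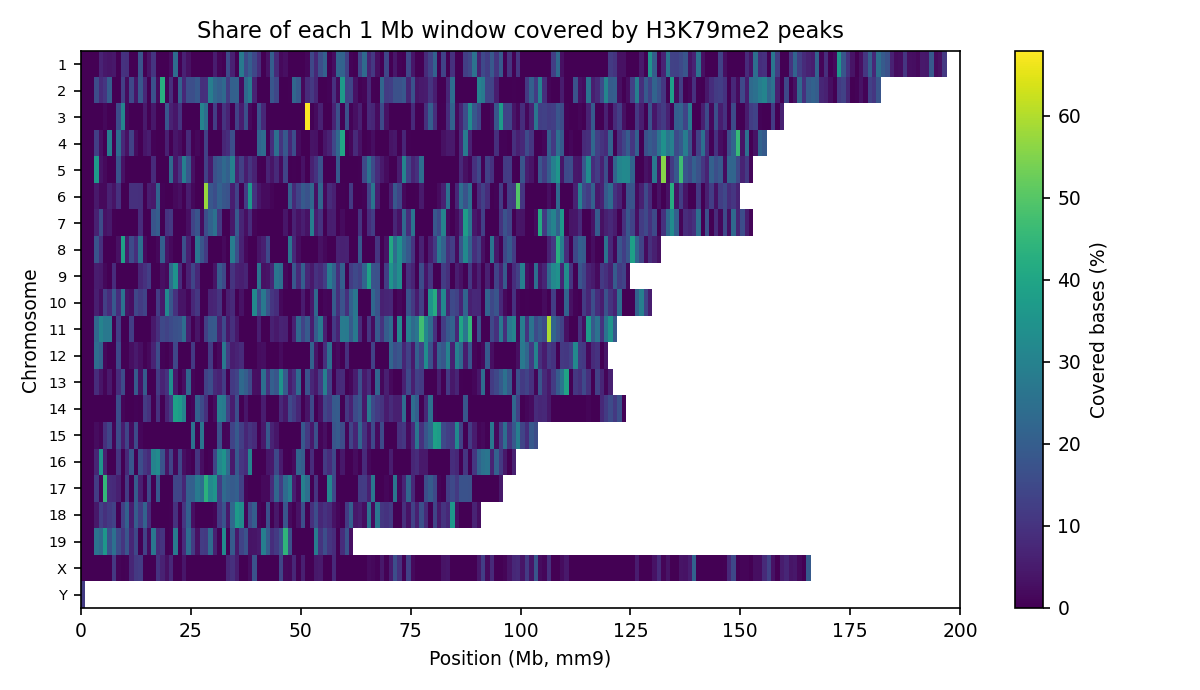
Each row is a chromosome and each cell a window of 1 Mb along it (mm9), coloured by the percentage of its bases inside H3K79me2 peaks; white lies beyond the last window with a peak. The brightest cell is 51 to 52 Mb on chromosome 3, at 67.9%, and X is dark along most of its length.

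Autosomes differed in their density of H3K79me2 peaks and in the share of their span covered. Chromosome 11 had the highest density, with 11.02 peaks per Mb and 14.03% of its span covered. Chromosome 19 followed with 10.5 peaks per Mb and 12.7% covered. Chromosome 3 had the lowest autosomal values, 5.47 peaks per Mb and 7.29% covered, although its share of peaks of at least 50 kb, 6.64%, was the highest of the autosomes. The median over the 19 autosomes was 7.72 peaks per Mb (SD between autosomes 1.51) and 8.95% covered (SD 1.795). Chromosome 13 had the lowest median width and median fold of the autosomes, 3.68 kb (interval 3.145 to 4.086) and 2.08 (2.03 to 2.12). Neither rank was settled by these intervals. The median width on chromosome 12 was 3.73 kb (3.053 to 4.449), and the median fold on chromosome 18 was 2.11 (2.06 to 2.17). Chromosome 13 also had the most peaks per protein-coding gene of the autosomes, 1.24. On chromosome 13, 439 peaks had a fold under 2 and 219 a fold of at least 4, a ratio of 2.005. In the other autosomes this ratio lay between 0.905 on chromosome 11 and 1.54 on chromosome 18.

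The X chromosome had fewer H3K79me2 peaks per Mb and a smaller share of its span covered than any autosome. These values are not scaled for the number of X copies in the pool, which the labels do not give. X had 562 peaks, or 3.54 per Mb, which was 0.459 times the autosome median (0.422 to 0.498, exact binomial 95% interval for the count of X peaks). Its peaks covered 3.06% of its span, against 7.29% on the least covered autosome. The median fold on X, 2.26, lay within the autosomal range of 2.08 to 2.57, but the folds are not alike: 99.1% of X peaks, against 16.4% of autosomal ones, were set against the lowest control background in the list. High pileups were rare on X: 0.712% of its peaks (exact interval 0.194% to 1.81%) reached 100 reads, against 7.24% of the 18418 autosomal peaks and 5.25% on the lowest autosome. The highest pileup on X was 108.1 reads, whereas the autosomes' highest values ran from 170.9 to 280.6. Wide peaks were rare too, with 2.14% (1.11% to 3.70%) at least 50 kb wide on X and 4.68% on the autosomes. The lowest autosome, chromosome 7 at 3.17%, lay inside the interval of X. The median width on X, 3.83 kb, and its share of peaks with a fold of at least 4, 23.5%, lay inside the autosomal ranges, whose lowest values were 3.68 kb and 21.3% on chromosome 13. The most covered 1 Mb window of X, 139 to 140 Mb, reached 21.4%. Per protein-coding gene of the GRCm38 table, X had 0.582 peaks, above chromosome 7 at 0.575 and below the other 18 autosomes.

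**Figure D3:**
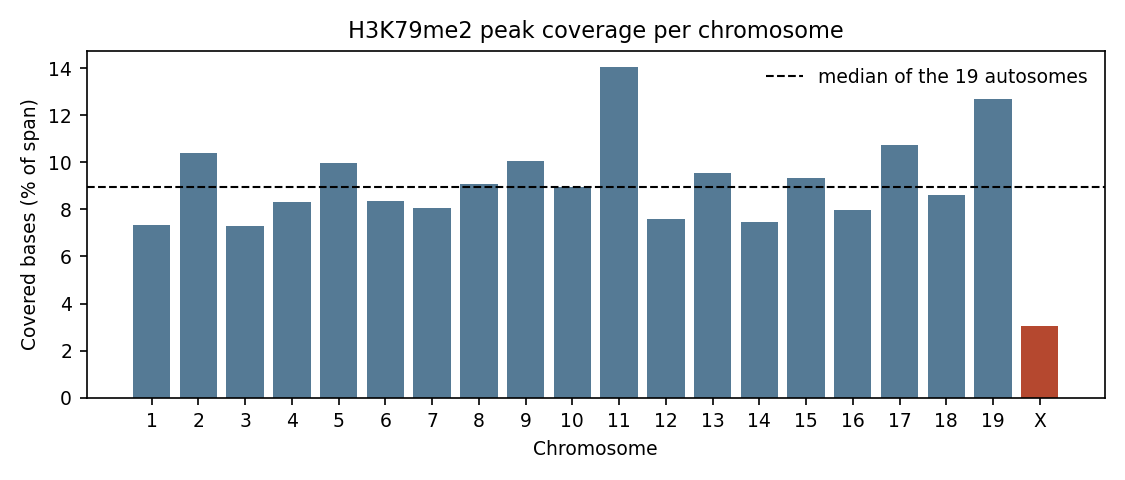
Bars give the percentage of each chromosome's span, from its first to its last peak, that lay inside H3K79me2 peaks; the dashed line is the median of the 19 autosomes, 8.95%. Chromosome 11 is highest at 14.03% and X lowest at 3.06%; Y is left out because its peaks span 0.389 Mb.

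**Figure D4:**
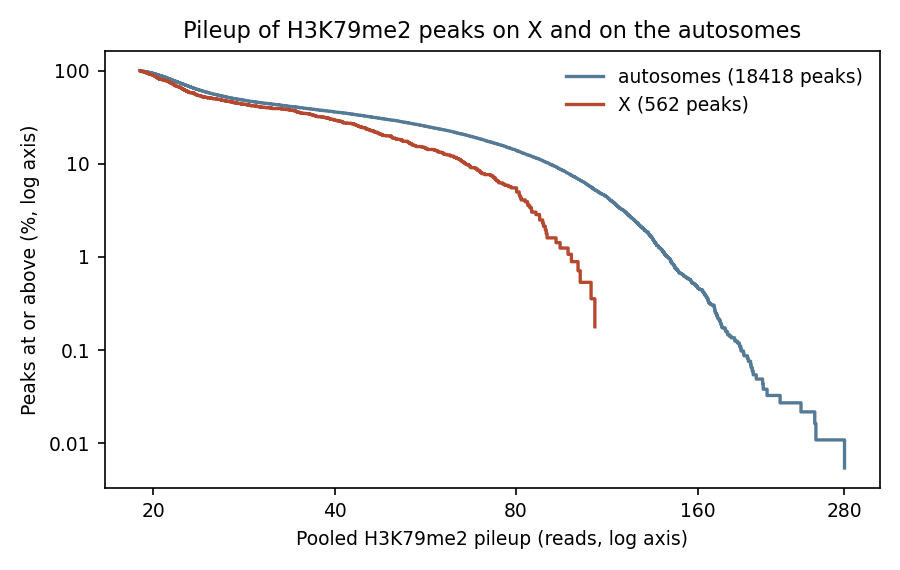
The curves give the percentage of peaks, on a log axis, whose pooled H3K79me2 pileup is at or above the value on the horizontal log axis, for the 18418 autosomal peaks and the 562 peaks of X. The curves start together at 19 reads and the X curve ends at 108.1 reads, the autosomal one at 280.6 reads.

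The Y chromosome held 12 peaks, all between 234286 and 622950, which covered 117.4 kb. The widest, from 534147 to 582053, spanned 47.9 kb with a fold of 4.78 and a −log10 q of 21.4. The next, from 598073 to 622950, was 24.9 kb wide with a fold of 4.16. Of the other 10 peaks, a region of 2.93 kb from 234286 to 237219 was the strongest, with a fold of 3.68. The Y peaks were described after their values were seen.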

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

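No paired analysis was possible because the deposited list pools the libraries, which also rules out leaving out a replicate. Gene overlap, genes marked and gene lists were not run for want of an mm9 annotation. The call threshold decided the size of the list: 8548 peaks had a −log10 q of at least 5, 6921 of at least 10, and 5571 a fold of at least 4, against 18992 as deposited; merging across 3 kb left 13365. The median width of 4416 bp moved to 15219 bp at a −log10 q of at least 10, 17211 bp at a fold of at least 4 and 8043 bp after merging across 3 kb. The median fold of 2.28 moved to 5.57 at a −log10 q of at least 10 and to 2.37 for peaks of at least 500 bp. The ratio of X to the autosome median, 0.459 for peaks per Mb, was 0.342 for covered bases, 0.41 at a −log10 q of at least 10, 0.635 per protein-coding gene and 0.61 per gene without olfactory and vomeronasal receptor genes, below 1 under these 4 alternatives. The width and fold relation kept its sign and passed 0.05 under its 5 alternatives (highest permutation p 0.001, the smallest 1000 resamples can give), with rho down from 0.78 to 0.34 at a −log10 q of at least 10. Merging across 1 kb joined no peaks, since the shortest gap is 1169 bp, and so tests nothing. The number of peaks, the median width and the median fold have no direction that could turn. No alternative turned the direction of the rho or of the X ratio. Of all 24 alternatives, 7 were chosen after seeing the data. Peaks below a pileup of 19 reads are not in the list, so weaker marking was not detectable at this depth.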

Other observations

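Of the tests in this part, those of gene number (apart from X peaks per protein-coding gene, a planned measure), the control background on X and Y, weak peaks at the lowest background, and repeated sequence were chosen after the result was seen; the others had not been seen when they were set. Across the 19 autosomes, the share of the span covered by H3K79me2 was higher on chromosomes with more protein-coding genes per Mb (gene numbers from GRCm38): Pearson's r was 0.72 (permutation p = 0.00086, BH 0.00086) and Spearman's rho 0.67 (p = 0.0019, BH 0.0019). Without chromosomes 7 and 11, the farthest from the median gene density, r was 0.87. With olfactory and vomeronasal receptor genes left out, r was 0.80 (p = 9e-05, BH 0.00018) and rho 0.69 (p = 0.0016, BH 0.0019), and without chromosomes 11 and 19 r fell to 0.55 (permutation p = 0.023). Chromosomes are not replicates, and 2 gene sets were tried.

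X had fewer H3K79me2 peaks per Mb than any autosome. Per protein-coding gene, X had 0.582 peaks, inside the autosomal range and above chromosome 7 at 0.575. Without receptor genes it had 0.586 (Poisson interval 0.539 to 0.637), 0.61 times the autosome median and below the lowest autosome at 0.724. Other gene families of X were still in the count, and this answer turned on the gene set. Genes per Mb argue against a lower number of genes as the whole account. X had 966 genes over a span of 158.6 Mb, and 959 without receptor genes. Chromosomes 12 (679 and 679 genes, 116.3 Mb) and 18 (511 and 510 genes, 87.4 Mb) had no more genes per Mb than X with either set. They held 6.74 and 7.14 peaks per Mb, against 3.54 on X. Whether gene number accounts for a part of the gap stays open. The control background fits fewer copies of X than of an autosome in the pooled input: of the 164 X peaks with a pileup of at least 40, 98.8% (exact interval 95.7% to 99.9%) sat at the lowest background the peak caller used, as did all 3 Y peaks of that pileup, against 0.301% of 6636 such autosomal peaks, so weak peaks reading the lowest background are not the reason. Over peaks of any pileup the shares were 99.1% on X and 16.4% on the autosomes, and all 12 Y peaks sat there. The 12 Y peaks, with up to 54.15 reads, a fold of 4.78 and a −log10 q of 21.4, argue for Y-bearing cells in the pool, although reads of like sequence placed on Y by mistake were not tested for.

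A pool with male cells in it is a candidate explanation of the background on X. The mice received the transformed CMP cells, and the labels give no sex for the animals or the cells. A scaling took 1, 2 or 3 of 3 equal parts of the pool to carry 1 X. These parts are assumed, since the labels do not say whether the libraries came from different mice. Autosomal peaks of at least 40 reads, scaled to such an X, would sit at the lowest background in 92.2%, 99.7% and 99.8% of cases. The first lies below the interval of X and the other 2 inside it. A scaled value rests on assumed backgrounds and excludes none of them. Whether the fewer reads from 1 X in every cell would be enough for the gap at this pileup was not settled. X had 171.0 peaks (145.8 to 199.3) of at least 40 reads per 1000 genes. That was 1.25 times the autosome median of 136.9 for at least 80 reads. The rule set beforehand asked whether X lay within the range of the autosomes at 80 reads, which was 93.8 to 164.7 in these data. The value lay above that range and its interval ran across the top, so the rule gave no clear answer. In this comparison X had no lack of peaks against the autosomes. Whether every cell carried 1 X also stays open.

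There were 18 peaks over a control background at least 2 times the lowest, on 8 chromosomes. Their median fold was 1.82, 14 of them had a fold under 2, and they include high pileups with little enrichment, such as 251.5 reads at a fold of 1.499 from 98502298 to 98503162 on chromosome 2. A gain of a chromosome segment in the leukaemias was tested on the 107 other peaks within 500 kb. Their median background was 1.06 times the lowest, which argues against a gain around most of them. The median pools the sites, so a gain at a few, or one shorter than the distance to the neighbours, would not show. Of the 18 peaks, 3 had no such neighbour. Repeated sequence collapsed in the assembly is a candidate explanation that stays open, because the sequence of these sites was not analysed here. An exception a reader could follow up is the pair from 90156658 to 90166814 and from 90168047 to 90174054 on chromosome 1: the second had the highest pileup of the list, 280.6 reads, over a background of 46.9 and still a fold of 5.88.

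If weak peaks were tails of wide strong regions, split off by the peak caller, an excess of them was predicted within 3 kb of strong peaks. This prediction was not met. It does not exclude such tails: the shortest gap in the list is 1169 bp, so nearer tails could not be counted. Permuting the folds also breaks any likeness of fold between neighbouring peaks, which by itself could lower the observed share. Of the peaks with a fold under 2, 11.8% had a peak of at least 4-fold within 3 kb, against 16.4% when folds were permuted among the peaks of each chromosome (0.723 times; 1000 permutations gave 15.1% to 17.6%). The share was also below the permuted one at 3 to 10 kb (0.852 times) and at 10 to 30 kb (0.904 times), and near it at 30 to 100 kb (1.02 times, one-sided permutation p = 0.18), the distance set beforehand for testing whether weak and strong peaks gather in the same wide regions, which leaves that open. At the 3 distances up to 30 kb the one-sided permutation p for a lower share was 0.001, the smallest these can give. The p at 30 to 100 kb was for a higher share, the direction predicted. The rest, 34.5% of weak peaks against 26.3% permuted, lay more than 100 kb from a strong peak; as the remainder of the other shares this is no test of its own.

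Over the autosomes the median control background per chromosome ran from 11.1 on chromosome 12 to 11.35 on chromosome 19, a ratio of 1.02. In 245 autosomal windows of 10 Mb with at least 15 peaks it ran from 10.7 to 11.98, with the highest at 70 to 80 Mb on chromosome 16.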
